A study of Mus musculus with 3 samples.

How the data were processed

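The series holds 3 ChIP-seq libraries from E14 mouse embryonic stem cells, a feeder-free line grown with LIF. One library was made with an antibody against Eset, the histone H3 lysine 9 methyltransferase also called Setdb1, from unperturbed cells. The other 2 were made with an antibody against H3K9me3, the trimethylated form of that lysine, from cells transfected with a control shRNA or with an shRNA against Eset. Per the labels' protocols, transfected cells were kept in puromycin at 0.8 µg/ml, cells were fixed with 1% formaldehyde for 10 min, and sonicated fragments averaged 500 bp. Per the labels, DNA of 20 immunoprecipitations was pooled for the Eset library and DNA of 3 for each H3K9me3 library, so each group has 1 library.

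The deposited read lists hold 1 line per aligned read, with a chromosome, a position, a strand, the read sequence, a match descriptor and a single-read alignment score given by the authors' aligner. The alignment score ran from 4 to 119 and was used only to describe the files. Coordinates are on mm8, per the submitters' processing notes. The aligner, its version and the peak caller are not given in the sources used here. The deposited peak list gives a chromosome, start and end for each Eset peak, with no height, so peaks were ranked here by their own Eset reads. It holds the peaks of the Eset library alone. Reads were 36 bases long, except in the second run of the control library, where they were 35. The control library had 3 lanes from 2 sequencing runs, the first with 2 lanes and the second with 1. The Eset and knockdown libraries had 2 lanes each, all from another run that they shared. Lanes of a library are technical repeats and were summed.

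The listed reads came to 11159322 for Eset, 12920863 for H3K9me3 in control cells and 10391825 for H3K9me3 in knockdown cells. Repeated reads at one position and strand were kept once per library, on the 19 autosomes and X. This removed 4.91%, 7.96% and 9.01% of the reads and left 10584071, 11852397 and 9417411. Each 5' end was moved 100 bp towards its 3' side, and counts were scaled to RPM, the share of these totals times 1000000. A count of 3 reads corresponds to 0.283, 0.253 and 0.319 RPM in the 3 libraries.

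Reads were counted within 1 kb either side of each peak midpoint, in windows 50 kb to either side of it (left out within 5 kb of a peak), and in 5 kb bins. A peak window was called marked when it held at least 3 times the genome mean and its exact Poisson 95% lower limit lay above that mean. Bins were called enriched when the mean of both H3K9me3 libraries was at least 3 times the median bin. A window or bin was called lower or higher in the knockdown library when its RPM differed at least 2-fold and the exact conditional binomial (Clopper-Pearson) 95% interval of the ratio excluded 1, with at least 20 pooled reads. Log2 ratios used a pseudocount of 0.5 reads; folds and intervals used the counts themselves. With 1 library per group there is no replicate check, no p-value is given for a difference between groups, and all intervals cover counting error only. PCR copies that start at different positions are not removed by the position filter. Intervals of medians are order-statistic 95% limits over windows, which are not independent replicates. The peak median was set against 10000 random lists of windows without a peak, drawn with the same distribution of the mean of both libraries (20 classes), and again matched on that mean and on GC (10 and 5 classes).

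The calling step was tested on simulated counts at the 4633 peak windows, in sets of 200 changed windows. Of windows lowered 2-fold, 3-fold and 4-fold, 55.0%, 85.7% and 96.6% of those tested were called lower, and 1.06% to 1.29% of unchanged windows were called. The counts were Poisson draws, so these rates leave out differences between runs. Between the 2 control runs, 18 windows were called lower and 78 higher of 3230.

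No genome sequence or annotation of mm8 was used here, and coordinates were not carried to another build. Peaks were therefore not assigned to genes, and Eset and H3K9me3 at gene starts, the gene lists and the level of the Eset gene itself were not analysed here. The libraries hold no RNA, so the depletion of Eset is taken from the labels. The rule for named items, fixed before the data were examined, was applied to regions in place of genes. It takes the 15 peaks with most Eset reads, and the 10 most lowered and 10 most raised peaks or bins with at least 50 pooled reads and the same sign in every pairing of a control lane with a knockdown lane. Groups of neighbouring peaks, marked peaks that stayed within 2-fold and unmarked peaks with most Eset reads were chosen after the values were seen.

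Motifs were planned for a genome sequence. In its absence the sequence of 501 bp around each Eset summit was rebuilt from the first 35 bases of the reads of all 3 libraries, which covered 80.8% of the bases at peaks (89.9% in the central 201 bp) and 44.3% in windows 2 kb away. Hits were counted on both strands per base searched, within 200 bp of sequence at the summit. The 4 words were fixed before the data were examined. Observed hits were also set against those expected from the dinucleotides of each window, computed from a first-order Markov chain in place of shuffling. A 20-base word was called repeated when reads placed it at 5 or more places (10 kb steps) in the genome, and a peak was called repeated when at least 20% of its searched words were. Shares have Wilson 95% intervals. Along each chromosome, the largest step between the means of its 10 Mb segments was set against 100000 permuted orders of the segments, a two-sided test with p-values adjusted over 20 chromosomes (Benjamini-Hochberg).

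Alternatives covered duplicates, scaling, lanes, count minimums, windows, bin size, thresholds and read placement. A GC correction, the removal of chromosomes 1 and 14, a comparison of the knockdown lanes and classes set by a single control run were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.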

Results

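Genome-wide binding of Eset and the H3K9me3 state of control and Eset knockdown cells were mapped by ChIP-seq in E14 mouse embryonic stem cells. The data comprised 3 libraries with 1 library per group. After repeated reads were removed, the Eset library held 10584071 reads, the H3K9me3 library of control cells 11852397 and that of knockdown cells 9417411. The mean window of 2 kb held 8.44, 9.45 and 7.51 reads in these libraries. No group had a replicate, so differences are given with intervals for counting error, and the runs and lanes of each library show the technical spread. All coordinates are on mm8.

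The first question was where Eset sat in the genome. The deposited list held 4633 Eset peaks with a median width of 545 bp (220 to 6923 bp), covering 2687921 bp. Peaks lay on all 19 autosomes and on X. Their density was 27.3 per 10 Mb on chromosome 17, 24.2 on chromosome 8 and 5.58 on X. Depth was lower on X, with 2.66% of the Eset reads on 152.4 covered Mb. Chromosome 1 held 7.62% on 190.3 Mb. Of the peaks, 17.0% had a neighbour within 10 kb, and 74 groups held 3 or more peaks, the largest 10. Peak windows held a mean of 5.17 Eset RPM, reads scaled to library size (5.15 to 5.19) and windows 50 kb away 0.896 (0.889 to 0.902), a 5.77-fold difference. The peaks are those of this same library, so an excess of its reads there follows from the choice of windows and is no test of binding. The windows at the 1st and 99th percentiles held 1.89 and 19.9 Eset RPM.

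The 15 peaks with most Eset reads were led by chromosome 17, 39450952 to 39456991, with 134 Eset RPM (127 to 141). The next were on chromosome 7 at 127401839 to 127403742 (50.5 RPM, 46.3 to 54.9) and on chromosome 10 at 12780391 to 12781837 (45.7, 41.8 to 49.99). A group of 5 peaks on X, 165313791 to 165337726, held 3 of the 15. H3K9me3 at these 15 peaks differed widely in control cells. The X peak at 165320855 to 165324650 held 142 H3K9me3 RPM (136 to 149). The peaks at chromosome 8, 73558475 to 73559378, and chromosome 4, 136996615 to 136997431, held 1.01 (0.52 to 1.77) and 1.10 (0.58 to 1.88), near the genome mean of 0.798. The peaks on chromosome 17 at 39450952, chromosome 7 at 82647149 and chromosome 9 at 123784117 held over 30 RPM in each of the 3 libraries, as did the X peaks, except the one at 165325209, with 26.2 in knockdown cells. No input library was used here to tell copy number from enrichment.

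**Figure D1:**
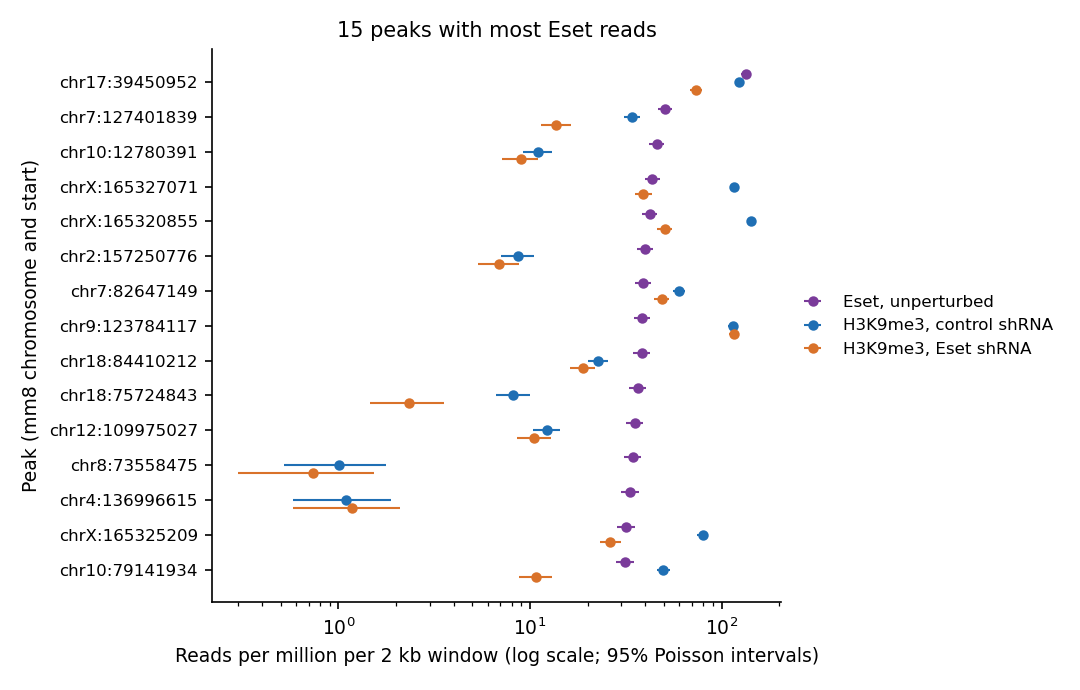
RPM per 2 kb window (x axis, log scale) in the 3 libraries at the 15 peaks with most Eset reads (y axis, mm8 chromosome and start), with bars for 95% Poisson intervals. At chromosome 9, 123784117, both H3K9me3 libraries lie near 115, and at chromosome 10, 79141934, knockdown cells lie at 10.7 against 49.7 in control cells.

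The second question was how often Eset sites carried H3K9me3 in control cells. Of the 4633 peak windows, 2850 (61.5%, 60.1% to 62.9%, Wilson) were marked, against 539 of 8901 windows 50 kb away (6.06%, 5.58% to 6.57%). A further 911 peaks were above the genome mean without being marked, and 872 (18.8%) lay below it. These classes were set on control reads near the midpoint, which fixes part of the control profile there. In knockdown cells, whose reads did not set the classes, H3K9me3 at marked peaks was 0.455 RPM per 250 bp at the midpoint and 0.128 at 5 kb on the side of lower coordinates. At the 872 peaks below the mean it was 0.118 and 0.106. Eset at the midpoint was 2.67 at marked peaks and 3.48 at those below the mean. Strong Eset peaks without the mark included chromosome 11, 102918616 to 102919345 (228 Eset and 6 control H3K9me3 reads), chromosome 6, 122667869 to 122668814 (213 and 0 reads) and chromosome 15, 102498836 to 102499661 (211 and 4 reads). A count of 0 in the control library allows up to 0.253 RPM when set at 3 reads, and 0.31 by the exact Poisson 95% interval.

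**Figure D2:**
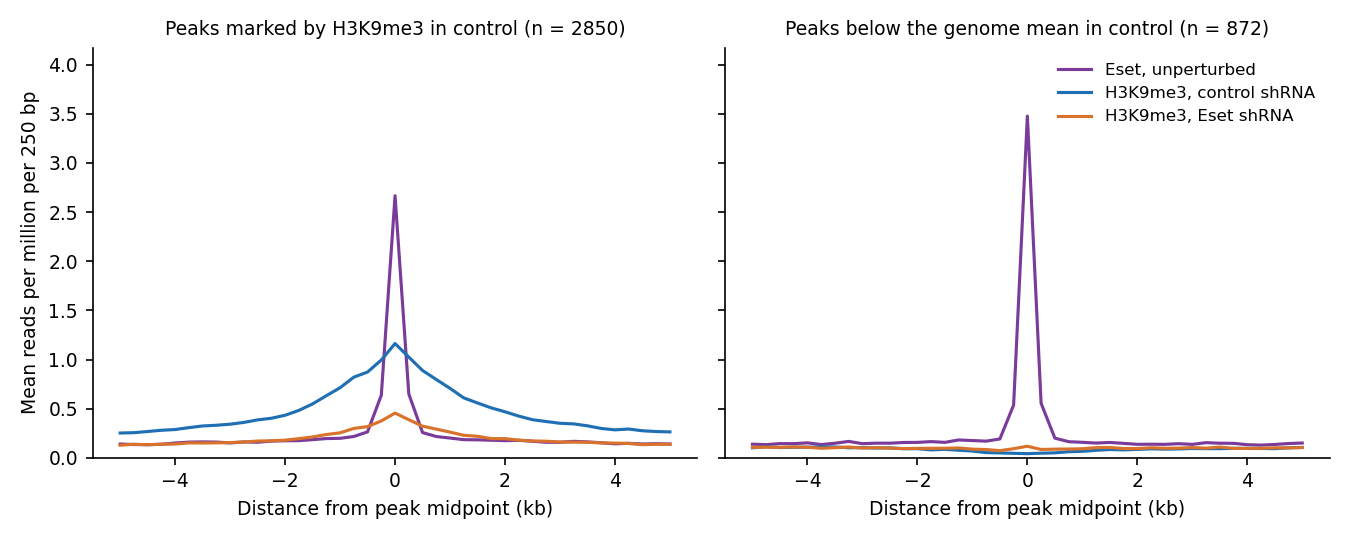
Mean RPM per 250 bp (y axis) against distance from the peak midpoint in kb (x axis) for the Eset library and both H3K9me3 libraries, at the 2850 peaks marked in control cells (left) and the 872 peaks below the genome mean (right). At marked midpoints H3K9me3 was 1.16 in control and 0.455 in knockdown cells.

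The third question was whether H3K9me3 at Eset peaks changed in the knockdown. H3K9me3 was lower at 2261 of the 3688 peak windows tested (61.3%), higher at 87 (2.4%) and neither at 1340. The median log2 ratio of knockdown to control was -1.29 (-1.32 to -1.25), a 2.44-fold loss. Of the 2850 marked peaks, 2118 (74.3%) were lower, and 1116 were also marked in knockdown cells. Of all 4633 peak windows, 1204 (25.99%, 24.7% to 27.3%) were marked in knockdown cells. Mean H3K9me3 at peaks was 4.86 RPM in control and 2.05 in knockdown cells. In windows 50 kb away it was 0.925 and 0.823, and 533 of 2917 tested (18.3%) were lower and 128 (4.4%) higher. The median of the peaks lay below all 10000 random lists of windows without a peak at the same mean level, whose medians ran from -0.73 to -0.58. Matched on GC as well, the lists ran from -0.71 to -0.56.

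Lower windows were far fewer between runs of a library than between the libraries, but higher windows were as frequent between the control runs. The second control run set against the first had 18 windows lower and 78 (2.4%) higher of 3230. The knockdown lanes against each other had 15 lower and 18 higher of 1558. The median 5 kb bin was 0.33 higher in knockdown cells on the log2 scale, so ratios relative to that bin lie 0.33 below those printed. Centring on the median ratio of all bins and scaling on background bins left 38 and 16 windows higher, against 87.

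**Figure D3:**
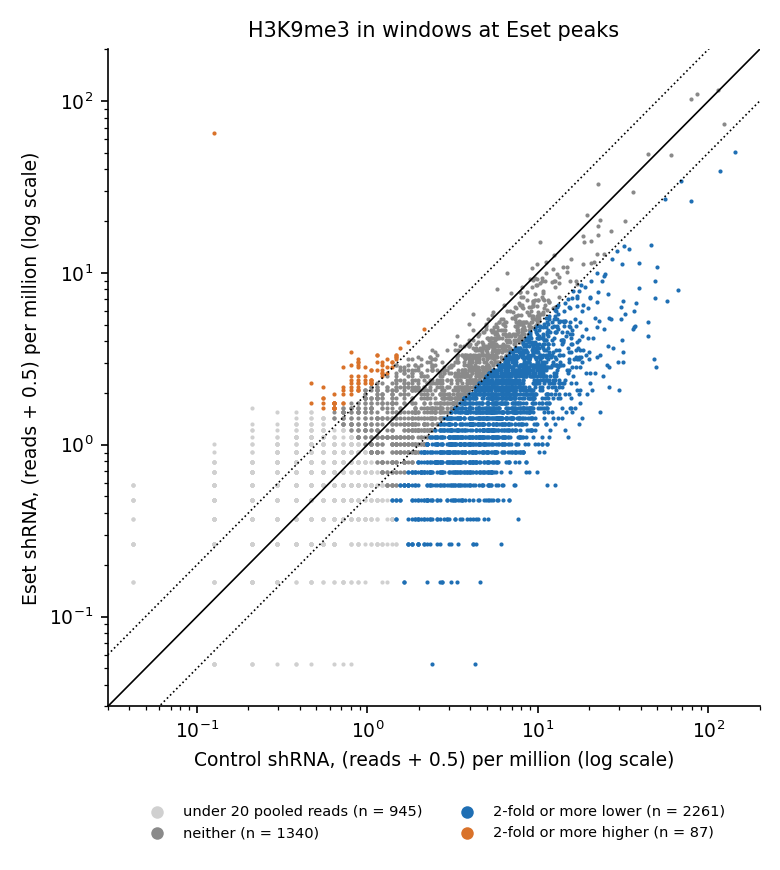
H3K9me3 reads (with 0.5 added) as RPM in control cells (x axis) and knockdown cells (y axis), both on log scales, in 4633 windows at Eset peaks, with a solid line at equal values and dotted lines at 2-fold differences. Of the windows 2261 windows were lower, 87 higher, 1340 neither, and 945 had under 20 pooled reads, and the point at upper left is the X peak with 1 control and 610 knockdown reads.

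The most lowered peak was on X at 145492563 to 145493171, with 50 reads in control and 0 in knockdown cells. It was 13.2-fold lower when the 0 is set at 3 reads, with an exact 95% lower limit of 10.4-fold. Chromosome 18, 65749475 to 65750843, went from 587 to 26 reads (17.9-fold lower, 12.1 to 27.7). Chromosome 7, 127027623 to 127028304, went from 148 to 5 (23.5-fold, 9.85 to 73.5), and chromosome 16, 93740610 to 93741189, from 133 to 5 (21.1-fold, 8.83 to 66.2). The others of the 10 most lowered peaks had 1 to 3 knockdown reads and were on chromosomes 16, 2, 10, 4, 13 and X, such as chromosome 10, 41479660 to 41480321, with 90 control and 3 knockdown reads (23.8-fold, 7.9 to 118). In 24 of the 74 groups of neighbouring peaks every window was lower. The group of 8 peaks on chromosome 17, 6585607 to 6600644, was 7.60-fold lower over its span (6.89 to 8.41). The 6 peaks on chromosome 5, 105953580 to 105964585, were 10.3-fold lower (8.70 to 12.2), and the 4 on chromosome 18, 65746561 to 65750843, 13.4-fold lower (10.5 to 17.4). The 10 peaks on chromosome 10, 82839234 to 82871626, had 9 lower windows and were 2.69-fold lower (2.48 to 2.92).

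Other strong Eset peaks differed by less than 2-fold in H3K9me3. This held, with the whole interval, for 175 of the 2850 marked peaks when scaled to library size. Background scaling takes 0.48 off each log2 ratio, and this count was not repeated with it. Of the 10 of these with most Eset reads, 4 were lower with an interval that excluded 1: chromosome 17, 39450952 to 39456991 (1.68-fold, 1.53 to 1.84), chromosome 7, 82647149 to 82648334 (1.24-fold, 1.10 to 1.39), chromosome 15, 72636568 to 72638236 (1.36-fold, 1.06 to 1.76) and chromosome 17, 12584580 to 12586415 (1.37-fold, 1.04 to 1.82). For the other 6 the interval included 1. Of these, the peak on chromosome 9 at 123784117 to 123786152 held 114 RPM in control and 115 in knockdown cells (ratio 1.01, 0.932 to 1.10). Chromosome 10, 12780391 to 12781837, held 10.97 and 8.92 (1.23-fold lower, 0.927 to 1.64). Chromosome 2, 157250776 to 157252282, held 8.61 and 6.90 (1.25-fold lower, 0.905 to 1.73). Chromosome 12, 109975027 to 109976659, held 12.2 and 10.5 (1.16-fold lower, 0.895 to 1.52).

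The rule for raised peaks found 4. The first, on X at 102389333 to 102389976, held 1 control read and 610 knockdown reads (768-fold higher, 137 to 30373), in a block of 490 bp with abrupt edges that was also present in the Eset library. The others were on chromosome 8, 108148670 to 108149318 (18 and 34 reads, 2.38-fold, 1.30 to 4.47), chromosome 2, 33453548 to 33454430 (20 and 37 reads, 2.33-fold, 1.32 to 4.23) and chromosome 1, 174162630 to 174163182 (25 and 44 reads, 2.22-fold, 1.33 to 3.78). With the GC correction these 3 were 1.89-fold, 1.85-fold and 1.76-fold higher, and with background scaling 1.70-fold, 1.67-fold and 1.58-fold, under the size rule in each case, while the X peak stayed above it. Centred on all bins, the peak on chromosome 8 was still called, at 2.03-fold.

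To keep the class of a peak apart from its ratio, peaks were classed by the second control run, and knockdown cells were compared with the first control run. The 2910 marked peaks had a median log2 ratio of -1.47 (-1.51 to -1.42), with 1996 of 2877 tested lower and 15 higher. The 832 intermediate peaks had -0.38 (-0.50 to -0.22). The 891 unmarked peaks had 0.43 (0.31 to 0.51), and of 92 tested 8 were lower and 12 higher. Over all 5 kb bins with reads, with both control runs pooled, the median log2 ratio was 0.23. Among marked peaks in quartiles of Eset reads, the median went from -1.16 (-1.24 to -1.09) in the lowest to -1.41 and -1.61 (-1.68 to -1.55), and was -1.66 (-1.78 to -1.55) in the highest. The last pair of intervals overlapped, and the share of lower peaks was 58.2%, 68.9%, 76.0% and 73.1% in this order.

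The fourth comparison covered H3K9me3 across the genome. Of 501754 bins of 5 kb with reads, 18111 (3.61%) were enriched, and they held 17.4% of the reads of control and 10.0% of those of knockdown cells. H3K9me3 was lower in 7171 (39.6%) and higher in 188 (1.0%), with a median log2 ratio of -0.76. Between the knockdown lanes, which have fewer reads, 143 bins were lower and 154 higher of 17619. Between the control runs 84 were lower and 64 higher of 18110. Higher bins were thus about as frequent within the knockdown library, but less frequent between the control runs. Scaling on background bins raised the lower bins to 11141 and left 18 higher. The 2115 enriched bins with an Eset peak had a median of -1.31 (-1.35 to -1.28) and 66.2% were lower; the 15996 without one had -0.69 (-0.70 to -0.67) and 36.1% were lower. With distance from the nearest peak the median went from -1.29 (-1.34 to -1.26) within 5 kb to -1.02 at 5 to 20 kb, -0.85 at 20 to 100 kb, -0.61 at 100 to 500 kb and -0.46 (-0.50 to -0.43) beyond. Mean control H3K9me3 of these bins also went from 13.7 to 8.0 RPM.

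**Figure D4:**
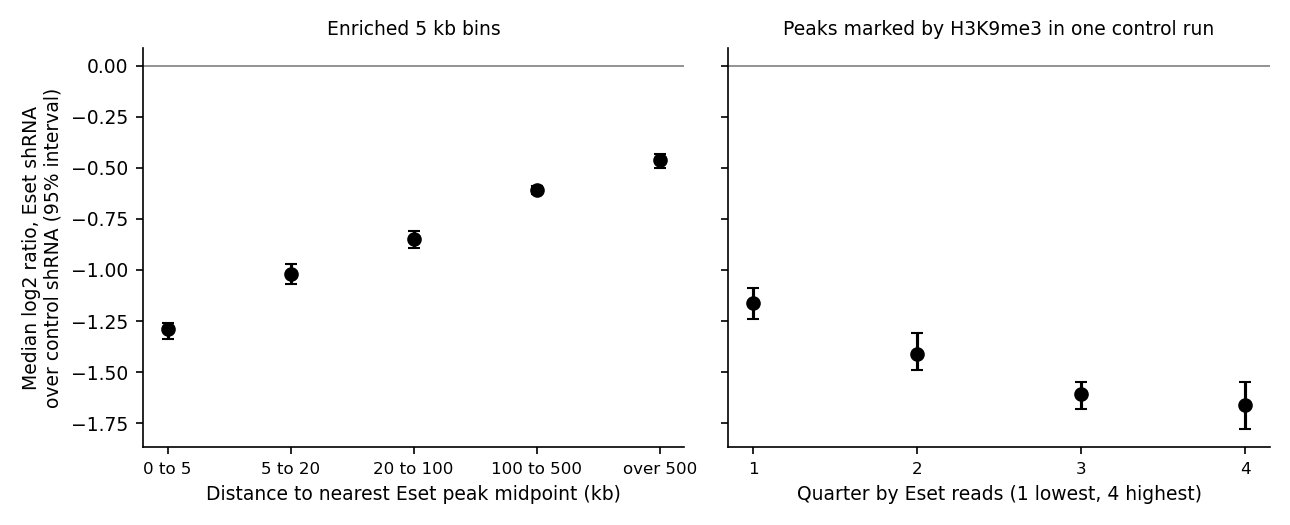
Median log2 ratio of H3K9me3 in knockdown to control cells (y axis) with 95% intervals of the median, for enriched 5 kb bins by distance to the nearest Eset peak (left) and for marked peaks by quartile of Eset reads (right). The medians run from -1.29 near peaks to -0.46 beyond 500 kb, and from -1.16 to -1.66 with more Eset reads.

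The most lowered bins included chromosome 2, 20585000 to 20589999 (185 control and 4 knockdown reads, 36.7-fold lower, 14.1 to 136), which holds one of the 10 most lowered peaks, and chromosome 4, 57970000 to 57974999 (221 and 8 reads, 21.9-fold, 10.9 to 51.5). On chromosome 13, 62175000 to 62179999, H3K9me3 went from 159 to 8 reads (15.8-fold, 7.82 to 37.2) with 9 Eset reads in the bin, fewer than the 21.1 of the mean bin. Apart from the X block, the most raised bins included chromosome 14, 99730000 to 99734999 (23 and 78 reads, 4.27-fold higher, 2.65 to 7.12), and chromosome 11, 71950000 to 71954999 (29 and 79 reads, 3.43-fold, 2.21 to 5.44). Of the 10 most raised bins, those at 99730000, 97595000, 113905000 and 95640000 were on chromosome 14, and 1 was on chromosome 1. Knockdown reads over these whole chromosomes were each 1.15-fold as frequent as in the Eset library within GC classes. On chromosome 14 the log2 ratios of 10 Mb segments averaged 0.01 before 70 Mb and 0.47 from there on, the part that holds these 4 bins.

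The last question was which sequence words Eset peaks held. CCACNAGGNGG, the core of the site of the insulator protein CTCF, had 17.7 times as many hits per base at summits as 2 kb away (9.15 to 39.4). It was found in 12.6% of the peaks below the genome mean of H3K9me3 (110 of 872, 10.6% to 15.0%), 5.60% of those between (51 of 911, 4.28% to 7.29%) and 0.46% of marked peaks (13 of 2850, 0.27% to 0.78%). TGCCGC, which the zinc finger protein ZFP57 binds when methylated, had 5.12 times the flank density (4.16 to 6.36). At marked peaks its hits were 2.76 times those expected from dinucleotides, against 1.04 and 0.95 at the other classes, though the share of peaks with the word was alike (10.1%, 9.55% and 9.63%). ACTACA, the core of the ZNF143 and THAP11 site, had 1.05 times the flank density (0.90 to 1.23), and its observed-to-expected ratio was 1.16 at peaks and 0.83 in the flanks. The octamer ATGCAAAT, bound by Oct4 and related factors, had 0.51 times (0.32 to 0.81), with 31 hits, and its observed-to-expected ratio was 1.28 at peaks and 1.37 in the flanks. With 100 bp at the summit its density ratio was 0.60 with an interval that included 1 (0.30 to 1.16). H3K9me3 was lower at 15 of 49 tested peaks with the CTCF word (30.6%, 19.5% to 44.5%) and at 2246 of 3639 without it (61.7%, 60.1% to 63.3%). These groups started from unlike levels. Of all peaks of these kinds 7.5% and 63.6% were marked, with median control H3K9me3 of 0.59 and 3.8 RPM.

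**Figure D5:**
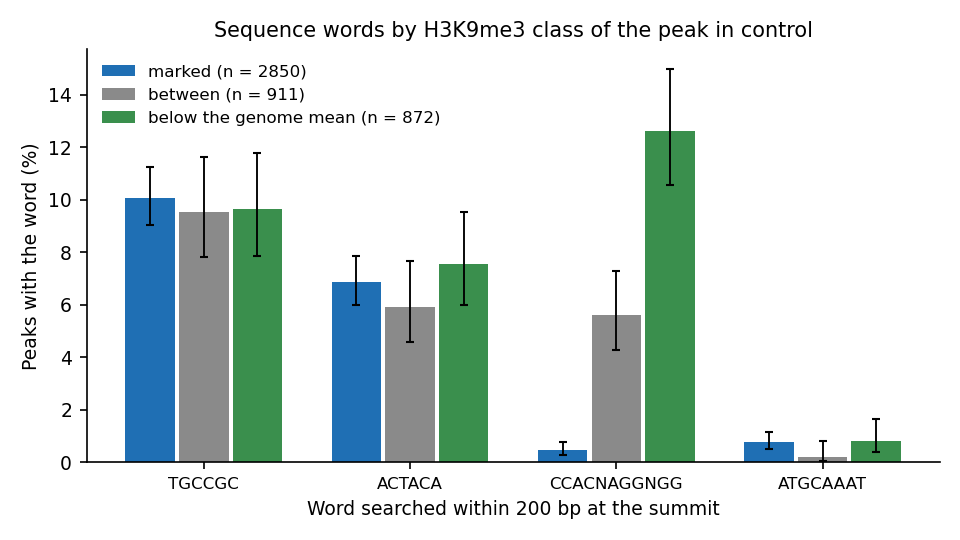
Share of Eset peaks (y axis, percent, with Wilson 95% intervals) that held each word within 200 bp at the summit (x axis), for peaks marked by H3K9me3 in control cells, between, and below the genome mean. The CTCF core word was in 0.46%, 5.60% and 12.6% of these classes.

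Marked peaks were also richer in repeated sequence. Of those with enough searched bases, 41.0% (39.2% to 42.8%) held words found at many other places, against 22.1% (19.5% to 24.9%) of peaks between, 4.8% (3.5% to 6.4%) of peaks below the genome mean and 7.9% (7.1% to 8.8%) of windows 2 kb away. H3K9me3 was lower at 62.1% of the 1326 tested peaks with repeated sequence and at 54.2% of the 1357 without any repeated word. Their median log2 ratios had overlapping intervals, -1.22 (-1.27 to -1.16) and -1.16 (-1.25 to -1.09), and 82.8% and 41.0% of all peaks of these kinds were marked. Reads listed here have a single position, so copies of a repeat that reads cannot tell apart are under-represented. Places of a word were counted among the reads of all libraries, including both H3K9me3 libraries. Words of repeats rich in H3K9me3 may thus be called repeated more easily, which was not tested.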

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

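The GC correction at peaks, the matched random lists, the tests of spread and amplification in the X block and the tests on chromosomes 1 and 14 were chosen only after results were seen, and the test of a vector copy after the block was seen.

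Reads outside the main measurement stood above the control library in 3 cases. Mitochondrial reads were 264 times as frequent in the Eset library as in the control library (191 to 375; 8424 against 37 reads). In the knockdown library they were 5.98 times as frequent (4.18 to 8.77; 178 reads). Reads on the Y chromosome were 1.21 times as frequent in the knockdown library (1.17 to 1.25; 7016 against 7204 reads), and 0.57 times as frequent in the Eset library (0.54 to 0.59).

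H3K9me3 was lower at 2261 of 3688 peak windows in the knockdown library. A difference of the size seen between the control runs is argued against, since those runs differed at 96 windows. The knockdown lanes came from another run than either control run, so an effect of that run could not be told apart. Lower enrichment at every marked region alike is argued against by random lists matched on mean and GC, the lowest of which lay 0.58 above the peak median on the log2 scale. After the GC correction 2461 windows were lower. A loss of H3K9me3 at Eset sites after depletion of Eset stays open as a hypothesis, and with 1 library per group it is confounded with any other difference between the pooled preparations.

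A block of 490 bp on X, 102389440 to 102389929, held 610 knockdown reads, 63 Eset reads and 0 control reads. Amplification copies are argued against, since the block stood at 332 times the genome mean with 1 read kept per position and strand. Spread of H3K9me3 from a new site is argued against, since the density within 1 kb outside was 0.0004 of that inside, against a median of 0.87 and a lowest value of 0.005 at the 50 peaks with most H3K9me3. A vector copy of this segment may give such edges, but its test was void in the knockdown library: the strands lay 29 bp apart, and 9 bp apart in the median of those 50 peaks. In the Eset library the strands of the block lay 60 bp apart, from 63 reads. The median there was 131 bp at the 50 peaks with most Eset reads. A vector in knockdown cells alone would leave no control reads, but does not account for the Eset reads from cells labelled unperturbed. The Eset and knockdown libraries shared a sequencing run that the control library did not, so an effect of that run could not be told apart. The source stays open.

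Knockdown reads were more frequent on chromosomes 1 and 14, each 1.15-fold against the Eset library within GC classes. GC content is argued against by the log2 ratio to control within GC classes, 0.17 or more on both, and a difference between runs by the ratio to the Eset library of the same run, 0.20 on both. On chromosome 1, 95% of the 10 Mb segments lay above the median segment against the Eset library. Segments averaged 0.14 before 70 Mb and 0.24 from there on against that library, but 0.00 and 0.25 against control. The first segment was negative against control on most chromosomes, such as -0.507 on chromosome 3, but not on chromosomes 2, 12, 16 and 19. A gain of chromosome 1 in part of the knockdown cells was thus neither shown nor excluded. On chromosome 14 the log2 ratios of segments to the Eset library averaged 0.01 before 70 Mb and 0.47 from there on (-0.01 and 0.42 to control), a step of 0.46 against 0.29 at most on any other chromosome, with a permutation p of 0.00268 over segment orders and 0.054 adjusted over 20 chromosomes; a first test, of the SD of segments, had given 0.27 against 0.20 at most elsewhere. The excess lay mainly in the distal part. A gain of the whole chromosome would raise both parts alike. The means of 0.01 and -0.01 before 70 Mb argue against such an even gain in this 1 knockdown library. The test of the step did not exclude it, since its adjusted p missed 0.05. Apart from gains of these chromosomes no biological explanation was tested.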

How the results depend on the processing

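The tests of the GC correction, the removal of chromosomes 1 and 14, the knockdown lanes set against each other, the single-run classes and the split of bins by Eset peak were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Alternatives set out for gene starts and for gene lists, and the overlap of peaks with gene starts, were not run, since no mm8 annotation was used here. At peaks, the count of lower windows stayed within 1.5 times of 2261 in 14 of 18 settings, from 1853 to 2848. The others were the peaks as deposited (1396), the smaller set of peaks above the median of Eset reads (1148), the control runs (18) and the knockdown lanes (15). The control runs and the knockdown lanes hold no biological difference, so their counts do not measure how stable the result is. Except where a setting is given its reason, the cause of a change was not tested.

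At peaks, lower windows, higher windows and the median log2 ratio were 2261, 87 and -1.29. With all reads the median was -1.33. Background scaling gave 16 higher and -1.77, and centring on all bins 38 and -1.52. The second control run alone gave 16 higher and -1.43, knockdown lane 1 alone 46 and -1.33, and lane 2 alone 38 and -1.33, each with fewer reads. No minimum of pooled reads gave -1.05; a minimum of 50 gave 4 higher and -1.50, with 2561 windows tested. The peaks as deposited gave 1396 lower, 7 higher and -1.43, with 2216 tested, and 2.5 kb either side gave 140 higher and -0.98. The peaks above the median of Eset reads gave 1148 lower and -1.43 from fewer peaks. The GC correction gave 33 higher and -1.44. Peaks marked in the second control run gave 15 higher and -1.47. As a measure with no biological difference, the control runs gave 18 lower and a median of the other sign, 0.10, and the knockdown lanes 15 lower, 18 higher and -0.06.

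In bins, the values were 7171, 188 and -0.76. With all reads the median was -0.79. Background scaling gave 11141, 18 and -1.24, and centring 65 higher and -0.99. The second control run alone gave 308 higher and -0.79. The GC correction gave 104 higher and -0.88, and removal of chromosomes 1 and 14 gave -0.80. Bins of 2 kb gave 25156, 2206 and -0.65, and bins of 10 kb 2432, 24 and -0.79, from other numbers of bins (66417 and 6098). At 5 times the genome median, with 4019 bins, the values were 2171, 10 and -1.07. Bins with an Eset peak gave 1400, 10 and -1.31, and those without one -0.69. The control runs gave 84 lower, 64 higher and a median of the other sign, 0.03; the knockdown lanes gave 143 lower, 154 higher and 0.01, also of the other sign. Higher windows were thus about as frequent between the control runs (78 of 3230) as between the libraries. Between the knockdown lanes (18 of 1558) they were less frequent. Higher bins were about as frequent between the knockdown lanes (154 of 17619), which have fewer reads. They were less frequent between the control runs (64 of 18110).

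Marked windows numbered 2850, and 1402 at the peaks above the median of Eset reads, which is a smaller set. The 5.77-fold Eset density over windows 50 kb away became 6.30 with all reads, 16.3 in the peaks as deposited, 3.25 within 2.5 kb and 7.97 at the peaks above the median of Eset reads. The density of TGCCGC over flanks went from 5.12 to 3.53 with 500 bp at the summit; the ratios of the other words stayed within their first intervals. The interval of ATGCAAAT, 0.32 to 0.81, came to include 1 with 100 bp (0.60, 0.30 to 1.16) and reached 1.00 with 500 bp (0.75, 0.56 to 1.00). Depth limits the calls: 945 of 4633 peak windows had under 20 pooled reads and were not tested.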

Other observations

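All tests in this part were chosen after seeing the data. The ratio of H3K9me3 in knockdown to control cells differed with the base composition of the peaks. In the quartile of peaks with the lowest density of CpG, 660 of 936 tested (70.5%, 67.5% to 73.3%) were lower and 3 higher, with a median log2 ratio of -1.53 (-1.60 to -1.45). In the highest quartile, 319 of 879 (36.3%, 33.2% to 39.5%) were lower and 77 higher, with a median of -0.55 (-0.70 to -0.46), and 40.2% of its peaks were marked against 67.4% in the lowest. With the GC correction, 77.5% (74.7% to 80.0%) of the lowest and 41.4% (38.2% to 44.7%) of the highest quartile were lower, 1 and 29 were higher, and the medians were -1.66 and -0.78. The control runs also differed with composition: in the highest quartile the second control run had a median of 0.33 (0.28 to 0.38) against the first, with 44 of 599 higher, and in the lowest -0.02 (-0.05 to 0.00). Of the 10 strong Eset peaks that differed by less than 2-fold in H3K9me3, those on chromosomes 10, 2, 12, 6, 15 and 17 (at 12584580) held 3 to 5 copies of TGCCGC in the rebuilt sequence. Among marked peaks in the tenth with most Eset reads, 26 of 46 with 2 or more copies were lower (56.5%, 42.2% to 69.8%), 27 of 31 with 1 copy (87.1%, 71.1% to 94.9%) and 138 of 180 without the word (76.7%, 70% to 82.2%), with medians of -1.13, -1.53 and -1.77. The median CpG per 100 bp was 3.73, 3.47 and 1.44 in these groups, so they also differed in composition. The 46 include the peaks that prompted the comparison, so it is no independent test.

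Retroviral primer binding sites, the 18 bases at which a tRNA primes reverse transcription, were counted in the reads. The site for tRNA-Phe, used by IAP elements, was in 35 peaks and 1 flank window. Reads with it numbered 34.96 RPM in the Eset library (31.5 to 38.7), 12.7 in control (10.8 to 14.9) and 7.54 in knockdown cells (5.89 to 9.51), so H3K9me3 was at 0.59 times the control level (0.44 to 0.79). Of the 34 peaks with this site that were tested, 9 (26.5%, 14.6% to 43.1%) were lower, none was higher, and the median log2 ratio was -0.60 (-0.93 to -0.45). The site for tRNA-Pro was in 3 peaks, at 0.66 times the control level (0.30 to 1.38), and that for tRNA-Lys3 was in 2, at 0.30 times (0.07 to 0.91), from 17 control and 4 knockdown reads. The remaining sites had at most 17 H3K9me3 reads in either library, and their intervals included 1. Among words of 9 bases, CTAAGACAG was in 239 of the 2850 marked peaks against 10.8 expected from flanks, and 164 of these were lower. CCGCCTCAG was in 108 against 2.4, of which 38 were lower. Of the peaks with these words 65.3% and 82.4% were called repeated, against 7.9% of windows 2 kb away. Copies of a repeat may share a word, so these peaks are not independent occurrences of it. At peaks below the genome mean AGGGGGCGC was in 81 of 872 against 1.2 expected, a word that overlaps the CTCF site. Of these peaks 0.0% were called repeated.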
